A study of Mus musculus with 12 samples.

How the data were processed

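Gene expression was measured in CD4-CD8 double-negative thymocytes, purified by sorting, on 12 Illumina MouseWG-6 v2.0 BeadChip arrays, which read 1 sample per array in 1 colour. The labels put 6 arrays in the wild-type group, 3 in the group with a CD2-Lmo2 transgene and 3 in the group with the same transgene and a Lyl1 knockout. All mice were C57BL/6 and 2 months old per the labels. RNA was taken from the cells with a column kit and labelled by the manufacturer's protocol, per the labels' protocols. The labels do not say whether each array stands for a separate mouse, so the p-values measure the spread between these samples, which may in part be technical.

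The deposited table of raw values gives 1 intensity per probe and array on a linear scale. The same deposited table gives, per the file headers, a detection p-value beside each intensity, which states how often negative-control beads reach that brightness. BeadStudio and limma are named in the submitters' processing notes without versions, and how BeadStudio handled background is not given in the sources used here. The authors' value table holds log2 values. Its columns have medians of 4.88 to 4.89. Each of its columns matched 1 array of the raw table, with a correlation of at least 0.9999 against the log2 values computed here and a mean absolute difference of about 0.0525. Its scale, direction and lack of centring are known from this match, while its background method stays unknown.

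The raw table names 3 of the wild-type columns by the word wild-type and a replicate number, and the other 3 add the word NHD13, which no label explains. These 3 columns were used as wild-type arrays without a number, because their names begin with wild-type and the labels list 6 wild-type samples. They matched the columns of wild-type replicates 4 to 6 in the authors' value table, so the labels count them as wild-type. They are called the NHD13-named wild-type arrays, and the others wild-type replicates 1 to 3. 

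Intensities were background-corrected with a normal-exponential model fitted from the detection p-values, quantile-normalized over all arrays and put on the log2 scale with an offset of 16 (neqc in limma 3.58.1 under R 4.3.3). Of 45281 probes, 34885 carried 1 gene symbol in the platform annotation, 18 carried several and 10378 carried none. Of the probes with 1 symbol, 34807 matched a gene of the RefSeq mouse table (GRCm38), which was used for names and for the order of genes along a chromosome only. A probe was kept when its detection p-value was under 0.05 on at least 3 arrays, which left 20651 probes, 17126 of them with 1 symbol. Each gene was represented by its probe with the highest mean log2 intensity over all arrays, giving 10526 genes. The 3525 kept probes with no single symbol were left out of the comparisons. Symbols are those of the annotation and can be old.

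A linear model with a mean per group was fitted to all 12 arrays with limma (lmFit, contrasts, eBayes), leaving 9 residual degrees of freedom, and each pair of groups was compared with limma's moderated test, two-sided. Genes count as changed at a Benjamini-Hochberg adjusted p under 0.05. Changes are differences of mean log2 intensity with their standard errors (SE). Where a gene's probe was not above background (detection p under 0.05) on any array of the dimmer group, only a bound is given. It is the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value of any detected probe. Where another probe of that gene was detected in the dim group, the gene counts as above background there, and the bound is that of its brightest probe.

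Genes are named by a rule fixed before the data were examined, as were the comparisons, the gene lists and all alternatives except 3 stated with their results. The rule takes Lyl1 and Lmo2, the 10 largest changes in each direction per comparison among changed genes with a regular symbol and no overlap between the groups, up to 4 changed members of each list, and a fixed set of key genes of T-cell development and leukaemia. The 22 lists cover LMO2 complex partners, stem and progenitor genes, early thymic progenitor genes, early T-cell precursor leukaemia genes, T-lineage commitment, Notch targets, proliferation, quiescence, IL-7 and KIT signalling, the BCL-2 family, interferon-stimulated genes, stress genes, and markers of B cells, myeloid cells, dendritic cells, natural killer (NK) and innate lymphoid cells, gamma-delta T cells, double-positive thymocytes, mature T cells, erythroid and megakaryocyte cells, stroma and sex. Some genes stand on several lists. Each list was tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether the members move on balance in 1 direction. List p-values were adjusted over the 22 lists of a comparison.

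Chance values for the overlap between comparisons came from 100 simulated draws of unchanged groups, with the same spread per gene on every array. The alternatives were quantile normalization without background correction, the authors' value table, median scaling, no filter, detection p under 0.01, the mean of a gene's probes, every probe on its own, only the groups compared, array weights, a trended and robust variance, the replicate number as a block, and leaving out each array. Whether arrays share a slide is not given in the sources used here, so no slide block was fitted.

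Between 37.9% and 43.0% of probes were detected per array, and median raw intensities lay between 111.9 and 205.5. The number of arrays and the brightness over background limit the precision. On simulated arrays with 10526 genes each, the procedure found 98.5% of genes changed by 2 on the log2 scale, 70.2% changed by 1 and 12.1% changed by 0.5 for transgenic against wild-type arrays. For knockout against transgenic arrays these shares were 97.0%, 52.2% and 4.55%, and for knockout against wild-type arrays 98.5%, 64.2% and 4.55%. Of unchanged simulated genes, 0.0582% were called in each comparison. The simulated noise was independent between arrays and genes, with few changed genes and no sets within a group. The wild-type arrays did form 2 sets, so these shares need not hold for the arrays used here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.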

Results

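Gene expression was compared in double-negative thymocytes, the immature thymic precursors that carry neither the CD4 nor the CD8 co-receptor, from mice of 3 genotypes. Wild-type mice gave 6 arrays, mice with a CD2-Lmo2 transgene gave 3, and mice with the transgene that lacked Lyl1 gave 3. Lmo2 is a LIM-only protein that bridges transcription factors in blood progenitors, and the CD2 promoter drives it in lymphoid cells. Lyl1 is a basic helix-loop-helix transcription factor that can join such complexes. The series title names a model of early T-cell precursor leukaemia driven by Lmo2 and asks whether it requires Lyl1. The 3 groups are called wild-type, Lmo2 and Lmo2 Lyl1-knockout arrays. On each array 37.9% to 43.0% of probes were detected, and 10526 genes were tested. Pearson correlations across probes between arrays of a group, over probes that are not independent replicates, were 0.960 to 0.993 for wild-type, 0.945 to 0.967 for Lmo2 and 0.982 to 0.990 for Lmo2 Lyl1-knockout arrays. All adjusted p-values for genes are from limma's moderated test with Benjamini-Hochberg adjustment.

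The targeted gene was read first. Lyl1 lay between 6.61 and 7.17 on the log2 scale on the 6 wild-type arrays, at 9.80, 9.97 and 11.39 on the 3 Lmo2 arrays and between 4.81 and 5.03 on the 3 Lmo2 Lyl1-knockout arrays. It was not above background on any knockout array, with detection p-values of 0.0769 to 0.249, and above it on every other array, as the genotype labels state. The 1 Lmo2 probe read 8.23 to 8.48 on wild-type replicates 1 to 3, 6.71 to 7.08 on the NHD13-named wild-type arrays, 5.72 to 7.27 on the Lmo2 arrays and 7.56 to 8.74 on the knockout arrays. Its log2 difference between Lmo2 and wild-type arrays was -1.09 ± 0.47 (SE; adjusted p = 0.165), with -1.81 against replicates 1 to 3 alone, past the threshold (0.0292), and -0.37 against the NHD13-named arrays alone (0.542). Whether this probe lies in the sequence that the transgene carries is not given in the sources used here, so it checks nothing about the transgene.

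**Figure D1:**
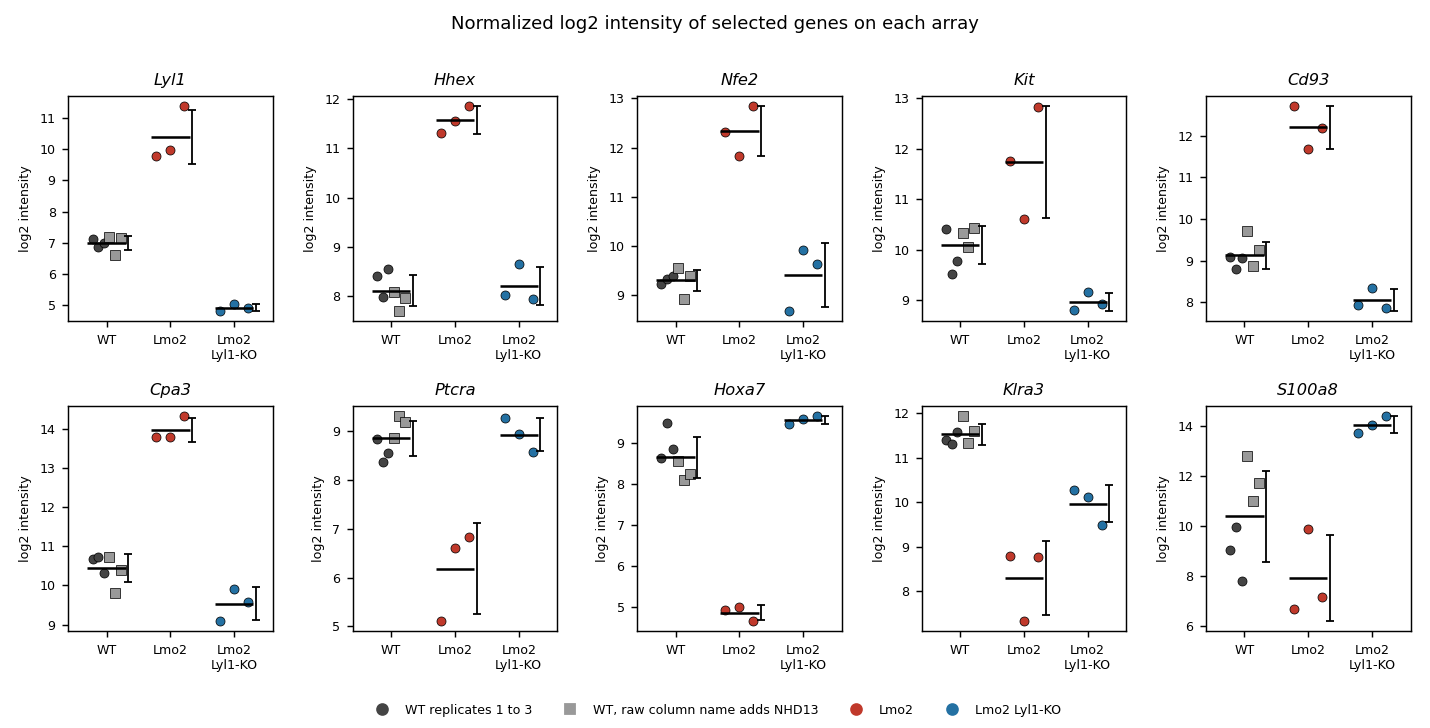
Log2 intensity of 10 genes on each of the 12 arrays, with a line at the mean of each group and bars of 1 SD. Lyl1, Hhex, Nfe2, Kit, Cd93 and Cpa3 were highest on the 3 Lmo2 arrays (red), where Ptcra, Hoxa7 and Klra3 were lowest, and S100a8 was highest on the Lmo2 Lyl1-knockout arrays (blue), at 13.69 to 14.39.

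Lmo2 against wild-type arrays asked what differed with the transgene in the sorted cells. Lyl1 rose by 3.40 ± 0.29 on the log2 scale (SE; n = 3 against 6; adjusted p = 7.36e-06). Hhex, a homeobox factor of early blood progenitors, rose by 3.46 ± 0.22 (adjusted p = 7.79e-07), and Nfe2, a leucine-zipper factor of the erythroid and megakaryocyte lineages, by 3.04 ± 0.27 (1.18e-05). Ptcra, the invariant chain of the pre-T-cell receptor, fell (-2.67 ± 0.34; adjusted p = 0.000227), as did Rag1, which cuts receptor genes for recombination (-1.52 ± 0.15; 3.05e-05). Of 18 natural killer and innate lymphoid markers 13 fell, and Hoxa7, a homeobox gene of early progenitors, was lower too. In all, 1324 genes changed, 701 up and 623 down, and of these 335 rose and 360 fell at least 2-fold.

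The largest increases were in genes with varied known roles. Tbx4, a T-box transcription factor, was at least 31.4-fold higher (adjusted p = 5.84e-06) and Lmcd1, a LIM-domain protein, at least 15.2-fold (6.35e-07); neither was detected on any wild-type array. Rpl3l, a muscle form of a ribosomal protein, rose by 4.92 ± 0.30 on the log2 scale, Gpr34, a receptor for lysophosphatidylserine, by 4.76 ± 0.28, and Acox2, a peroxisomal oxidase, by 4.75 ± 0.33. Olfm5 rose by 4.55 ± 0.38, Igf2bp3, a fetal RNA-binding protein, by 4.37 ± 0.40, and Fbln1, an extracellular matrix protein, by 4.25 ± 0.19. Agouti (symbol a) rose by 4.24 ± 0.24 and Myh10, a non-muscle myosin, by 4.22 ± 0.32. Of the 6 wild-type arrays, 3 detected Olfm5 and agouti, 4 Acox2 and 5 Rpl3l, Gpr34 and Myh10. The adjusted p-values of these 8 genes ran from 1.75e-07 to 1.42e-05.

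The largest decreases included a T-cell receptor beta segment, Trbv13-1 (-3.90 ± 0.37; adjusted p = 2.05e-05). Hoxa7 was at least 10.4-fold lower (1.17e-06) and Zfp518b, a zinc-finger gene, at least 8.15-fold lower (1.36e-07), both not detected on any Lmo2 array. Bahcc1 (-3.48 ± 0.47) and Gja1, a gap-junction protein (-3.41 ± 0.26), fell and were each detected on 1 of 3 Lmo2 arrays. Klra3 and Klra10, which encode Ly49 receptors of natural killer cells, changed by -3.24 ± 0.30 and -3.16 ± 0.29. Decreases were also measured for Ctla4, an inhibitory receptor of T cells (-3.01 ± 0.29, detected on 2 of 3 Lmo2 arrays), St6galnac3, a sialyltransferase (-3.01 ± 0.18), and Casp1, the inflammasome protease (-2.90 ± 0.33). The adjusted p-values of these 7 ran from 6.35e-07 to 0.000324. The other probes of some genes named for this comparison gave smaller changes, none past the threshold: -0.64 and -0.47 for Bahcc1, 1.19 for Kit, -0.63 for Bcl2a1d, 0.04 and 0.44 for Bbc3, -1.98 to -0.48 for Mpo, and 0.58 and 0.63 for Slc14a1. The 2 other probes of Cd8b1 gave -2.82 and -0.09, with 1 of them past the threshold. Those of Tk1 gave -0.98 and 0.15, neither past it.

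Among the lists of progenitor genes, 6 of 20 measured stem and progenitor genes rose and 3 fell (9 and 4 adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.162). Of the 14 early thymic progenitor genes that are silenced at T-lineage commitment, 5 rose and 2 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.582). The 5 were Lyl1, Hhex, Nfe2, Kit, the stem cell factor receptor (1.65 ± 0.38; adjusted p = 0.0122), and Cd93, a lectin-like receptor of early progenitors (3.07 ± 0.24; 4.12e-06). Bcl11a, a zinc-finger factor of lymphoid progenitors, fell by 1.88 ± 0.43 (0.012). Of 13 genes described for early T-cell precursor leukaemia, 4 rose and none fell, with the same counts over the list alone (camera adjusted p = 0.582). In both of these lists the median change was below 0 (-0.34 and -0.59) while the mean was above it (0.52 and 0.45), as was the direction camera gave. Mef2c, a factor on the leukaemia list, gave -1.19 ± 0.51 (0.16), and Spi1 was detected on 3 wild-type arrays and no Lmo2 array (0.149). Of the LMO2 complex partners, 3 of 12 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.178): Lyl1, the E-protein gene Tcf12 (0.72 ± 0.18; 0.0188) and the corepressor gene Cbfa2t3 (0.63 ± 0.14; 0.0126). Though camera called none of these lists, all of them passed fry. Its adjusted p-values were 0.00829 for stem and progenitor genes, 0.00829 for early thymic progenitor genes, 0.0093 for leukaemia genes and 0.00588 for LMO2 partners. Erg, Gata2 and Tal1 were not above background on 3 arrays, and Lck and Tcf7 were not analysed here.

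Of 9 erythroid and megakaryocyte genes, 4 rose and none fell, with the same counts over the list alone (camera adjusted p = 0.04; adjusted p = 0.41 with an estimated correlation; fry 0.0029), a call that ended without any 1 of wild-type replicates 1 to 3, without Lmo2 replicate 1 or 3 and against the NHD13-named arrays alone. They were Nfe2, the platelet chemokine gene Pf4 (at least 2.48-fold, not detected on any wild-type array), the urea transporter gene Slc14a1 (0.90 ± 0.23) and the platelet glycoprotein gene Gp9 (0.77 ± 0.21, detected on 1 wild-type array).

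Of 28 genes of T-lineage commitment and T-cell receptor signalling, 6 fell and 2 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.582). Beside Ptcra, detected on 2 of 3 Lmo2 arrays, these included the co-receptor chain gene Cd8b1 (-2.25 ± 0.25), the costimulatory receptor gene Cd28 (-1.72 ± 0.38) and Id3, an inhibitor of E proteins (-1.57 ± 0.23). Bcl11b, which fixes T-cell identity, gave -0.09 ± 0.13 (adjusted p = 0.693), Gata3 0.36 ± 0.21 (0.301), Cd3e 0.00 ± 0.10 (0.986) and Il2ra 0.55 ± 0.23 (0.149). Of 12 Notch receptors and targets, 2 fell, Ptcra and Nrarp (-0.59 ± 0.16), and 3 fell adjusted over the list alone (camera adjusted p = 0.71, direction down, with a median above 0). Notch1 gave 0.22 ± 0.17, Hes1 0.39 ± 0.24 and Dtx1 0.19 ± 0.31, none past the threshold. Of 13 double-positive thymocyte markers, 5 fell and 2 rose (5 and 6 over the list alone; camera adjusted p = 0.5), with Ets2 at -1.02 ± 0.16 and Dgkeos at -1.23 ± 0.13 beside Rag1 and Cd8b1. Of 15 mature T-cell markers, 3 fell, Ctla4, Icos (-1.69 ± 0.51, detected on 2 of 3 Lmo2 arrays) and Ly6c1 (-1.62 ± 0.28), and 4 fell and 1 rose over the list alone (camera adjusted p = 0.386). Of 10 gamma-delta T-cell markers, 2 rose and 3 fell (2 and 4 over the list alone; camera adjusted p = 0.916). They rose in Cpa3, a mast-cell carboxypeptidase also found in early progenitors (3.53 ± 0.24), and the transcription factor gene Sox13 (1.60 ± 0.18), and fell in Id3 and 5830411N06Rik (at least 2.10-fold lower), with a mean of the list above 0 and a median and camera direction below it.

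Natural killer and innate lymphoid markers fell together: 13 of 18 fell and none rose, 17 adjusted over the list alone (camera adjusted p = 2.86e-14; adjusted p = 0.282 with an estimated correlation; fry 0.000288). Examples were Klra3, Klra7 (-2.73 ± 0.40), the chemokine genes Ccl5 (-2.67 ± 0.29) and Xcl1 (-2.53 ± 0.37). Relative to the wild-type mean, the mean of this list was -1.33, -2.43 and -1.49 on the 3 Lmo2 arrays. Whether the share of such cells among the sorted cells or expression within cells differed was not tested in any comparison between genotypes. The same holds for the dendritic and B-lineage markers. Of 16 dendritic markers, 3 fell, H2-DMa (-2.03 ± 0.35), Irf8 (-1.52 ± 0.29) and Siglech (-1.37 ± 0.27), and 5 fell over the list alone (camera adjusted p = 0.0011; adjusted p = 0.446 with an estimated correlation; fry 0.0242), a call that ended against the NHD13-named arrays alone (0.261). Of 13 B-lineage markers, 2 fell over all genes and over the list alone, Cd72 (-2.07 ± 0.32) and Blk (-1.30 ± 0.37; camera adjusted p = 0.304). Both of these lists also differed among wild-type arrays: 10 of 16 dendritic and 7 of 13 B-lineage markers were lower on the NHD13-named arrays than on replicates 1 to 3. Of 27 myeloid markers, 3 rose, among them the complement genes C1qb (1.92 ± 0.44) and C1qc (1.48 ± 0.42), and 2 fell, Fcer1g (-2.03 ± 0.24) and Mpo (-2.65 ± 0.67, detected on 1 Lmo2 array), with 3 and 3 over the list alone (camera adjusted p = 0.215). Of 5 stromal markers, 1 rose, Pdgfrb (1.75 ± 0.50), and 3 over the list alone (0.136). The 4 sex-linked genes gave no call (0.815). That list joins Xist with Y-linked genes, which differ between the sexes in opposite directions. Its test is therefore no check of sex in any comparison.

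Of 30 genes of S phase and mitosis, 2 fell, Ccne1 (-1.08 ± 0.31) and Tk1 (-0.67 ± 0.20), none adjusted over the list alone, and the list passed camera as lower (adjusted p = 0.00642; adjusted p = 0.704 with an estimated correlation; fry 0.0847), a call that ended without Lmo2 replicate 1 (0.163) or 3 (0.0708). Of 15 genes linked to quiescence, 5 rose and 1 fell (8 and 2 over the list alone; camera adjusted p = 0.0546). The cell-cycle inhibitor genes went both ways. Cdkn1c (1.76 ± 0.51; 5.21 on Lmo2 replicate 3 and up to 8.34 on the other 2, against 5.20 to 5.62 on wild-type arrays) and Cdkn2a (at least 1.99-fold, with its brightest probe detected on no wild-type array and another of its probes on 1) rose with Foxo3 (1.12 ± 0.17), and Cdkn1a fell (-2.42 ± 0.31). Cdkn1b gave 1.00 ± 0.46 (adjusted p = 0.192). In IL-7 and KIT signalling 2 of 12 rose, Kit and Stat5a (1.27 ± 0.19), and Cish fell (-0.99 ± 0.28), the same over the list alone (camera adjusted p = 0.916). Il7r gave 0.26 ± 0.21 and Myc -0.75 ± 0.26 (0.0793). In the BCL-2 family of 14 genes the pro-apoptotic gene Bbc3 rose (0.98 ± 0.20) and Bcl2a1b (-1.90 ± 0.25) and Bcl2a1d (-1.64 ± 0.30) fell, the same over the list alone (camera adjusted p = 0.121), with Bcl2 at -0.63 ± 0.39 (0.339), which read 7.55 on Lmo2 replicate 2 and 10.01 and 9.30 on the other 2 and gave 0.07 without replicate 2. Of 23 interferon-stimulated genes 1 rose, Rtp4 (1.02 ± 0.23), also over the list alone (0.304). Of 14 stress genes 1 rose, Dnajb1 (0.54 ± 0.14), and 2 fell, Egr2 (-1.59 ± 0.32) and Hsph1 (-1.13 ± 0.27), with 2 and 2 over the list alone (0.916). Further lists that camera did not call passed fry. They were quiescence (fry adjusted p = 0.000288), the BCL-2 family (0.0093), double-positive (0.00939), mature T-cell (0.0389) and stromal markers (0.0244).

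The 2 sets of wild-type arrays gave different counts: 750 genes changed against replicates 1 to 3 alone, 2429 against the NHD13-named arrays alone, and 600 of the 1324 changed the same way against both (319 up, 281 down). Lyl1, Hhex, Nfe2, Ptcra and Rag1 passed in both. Of the genes named above, Kit, Tcf12, Pf4, Slc14a1, Gp9, Cdkn1c, C1qb, C1qc, Bbc3, Dnajb1, Nrarp, Ccne1, Tk1, Cish, Blk, Icos and Mpo lost their call against replicates 1 to 3 alone, and Bcl11a, Cd28, Cdkn1c, Cish, Blk, Mpo and Pdgfrb against the NHD13-named arrays alone. Without Lmo2 replicate 1 or without Lmo2 replicate 3, Cbfa2t3 and Rtp4 lost theirs, Hsph1 did without replicate 3 and Bcl11a without replicate 2, and Cbfa2t3 and Rtp4 also did with arrays scaled to a common median. The value of Cdkn1c was 2.74 without Lmo2 replicate 3, and its call ended in 17 alternatives. Without 1 Lmo2 array the values of C1qc (0.85, replicate 1), Pdgfrb (1.08, replicate 3), Cish (-0.52), Icos (-0.99) and Blk (-0.80, all replicate 2) moved by over 1.5 times and their calls ended. Calls were gained by Mef2c against replicates 1 to 3 alone (-1.93; adjusted p = 0.0348; -0.45 and 0.475 against the NHD13-named arrays), Cdkn1b against the NHD13-named arrays alone (1.53; 0.0429) and with array weights, and Myc without Lmo2 replicate 1 (-0.96; 0.0483). Dtx1 gave -0.26 against the NHD13-named arrays alone (0.518). Some key genes not past the threshold rested on 1 Lmo2 array: without replicate 3 Gata3 gave 0.10, Il2ra 0.20, Hes1 0.08, Il7r 0.01, Dtx1 -0.10 and Myc -0.41, and Cdkn1b gave 0.42 without replicate 1 and the Lmo2 probe -0.69 without replicate 2.

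Lmo2 Lyl1-knockout against Lmo2 arrays asked what changed when Lyl1 was removed in the presence of the transgene. Hhex fell by 3.36 ± 0.25 on the log2 scale (SE; n = 3 against 3; adjusted p = 4.07e-06), and lower values were also measured for Nfe2 (-2.94 ± 0.31; 7.2e-05), Kit (-2.78 ± 0.44; 0.00121) and Cd93 (-4.15 ± 0.28; 1.88e-06). Ptcra rose by 2.74 ± 0.39 (0.00065) and Rag1 by 1.30 ± 0.18 (0.000424), and Hoxa7 was at least 19.6-fold higher (1.37e-06). In all, 1084 genes changed, 501 up and 583 down, of which 340 rose and 363 fell at least 2-fold. With arrays scaled to a common median, 60.5% of changed genes were up, against 46.2% here.

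The 10 largest increases were all in genes that granulocytes or macrophages are known to express. The neutrophil granule genes Lcn2, Ltf, Ngp and Camp rose by 7.02 ± 1.00, 6.89 ± 0.93, 6.88 ± 0.89 and 6.83 ± 0.90, and the calcium-binding alarmin genes S100a9 and S100a8 by 6.72 ± 1.20 and 6.14 ± 1.12. The chitinase-like genes Chil4 and Chil3 were at least 36.7-fold and at least 37.7-fold higher (the other 2 Chil3 probes gave 4.82 and 5.15), the formyl peptide receptor gene Fpr2 at least 25.2-fold higher, and Retnlg, a resistin-like hormone, rose by 5.06 ± 1.08. Adjusted p-values of the 10 ran from 0.000197 to 0.00893. Camp, Lcn2 and Ltf were detected on 1 of 3 Lmo2 arrays and Ngp and Retnlg on 2. Chil4 and Fpr2 were detected on none, and for Chil3 the brightest probe was detected on none and another on 1. Of 27 myeloid markers 15 rose and none fell (19 and 1 adjusted over the list alone; camera adjusted p = 3.61e-10; adjusted p = 0.287 with an estimated correlation; fry 0.00366).

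The 10 largest decreases were all in genes that were past the threshold as higher on Lmo2 than on wild-type arrays. Lyl1 was at least 36.9-fold lower (1.37e-06), Olfm5 at least 24.8-fold lower (1.16e-05) and Lmcd1 at least 16.2-fold lower (2.86e-06). Tbx4 (-5.44 ± 0.53), Fbln1 (-5.35 ± 0.22), Rpl3l (-5.21 ± 0.35), Acox2 (-4.96 ± 0.38) and Lcn4, a lipocalin (-4.58 ± 0.49), fell, as did Gpr34 (-4.48 ± 0.32) and Cpa3 (-4.44 ± 0.28). The adjusted p-values of these 7 ran from 1.23e-07 to 7.63e-05. Of the 3 knockout arrays, 1 detected Tbx4, Fbln1 and Acox2, and 2 detected Rpl3l. The other probes of some genes named for this comparison were not past the threshold: -1.24 for Kit, -0.41 and -0.38 for Bbc3, 0.53 for Il18r1, 0.31 and 1.02 for Cdkn1a, -1.17 for Aqp11, -0.95 for Trp53inp1, and -1.18 and -0.89 for Slc14a1. The 2 other probes of Cd8b1, whose brightest probe rose, gave 2.31 and -0.58, with 1 of them past the threshold as higher.

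In the stem and progenitor list 7 of 20 fell and 2 rose, Hoxa7 and Hoxa5 (at least 7.10-fold higher; 2.82e-07), with 8 and 4 adjusted over the list alone (camera adjusted p = 0.108). Of 14 early thymic progenitor genes 5 fell and 2 rose (5 and 4 over the list alone; camera adjusted p = 0.398, direction down, with a median of 0.38 and a mean of -0.82). Of 13 early T-cell precursor leukaemia genes 4 fell and 2 rose (4 and 4 over the list alone; 0.488, direction down, with a median of 0.42 and a mean of -0.51). Of the 12 LMO2 complex partners 2 fell, Lyl1 and Cbfa2t3 (-0.94 ± 0.17; 0.00263), and 4 fell and 2 rose over the list alone (0.104). Gata3 gave -0.78 ± 0.24 (0.0557), Bcl11a 1.49 ± 0.49 (0.082) and Mef2c 1.09 ± 0.59 (0.31). Of 9 erythroid and megakaryocyte genes 3 fell, Nfe2, Gp9 (at least 1.73-fold lower) and Slc14a1 (-1.05 ± 0.27), and the tetraspanin gene Cd9 rose (1.43 ± 0.27), with 4 and 1 over the list alone (0.108). Though camera called none of these lists, all of them passed fry. Its adjusted p-values were 0.0227 for stem and progenitor, 0.00366 for early thymic progenitor and 0.00676 for leukaemia genes. For LMO2 partners fry gave 0.00297 and for erythroid and megakaryocyte genes 0.0103. Lyl1, the knocked-out gene, is a member of all of these lists but the erythroid and megakaryocyte one. Part of their fall was therefore set by the genotype, and they were not tested without Lyl1.

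Of 28 T-lineage commitment genes 5 rose and 1 fell (5 and 2 over the list alone; camera adjusted p = 0.757, with a median below 0 and a direction of up), among them Cd28 (2.37 ± 0.44), Cd8b1 (2.06 ± 0.28) and Id3 (1.41 ± 0.27). Of 12 Notch receptors and targets 2 rose, Ptcra and Bcl6 (1.13 ± 0.32), and 1 fell over the list alone beside these 2 (0.814, with a median below 0 and a direction of up). Bcl11b gave 0.10 ± 0.15, Cd3e -0.06 ± 0.12, Notch1 -0.20 ± 0.19, Hes1 -0.65 ± 0.28, Dtx1 0.33 ± 0.36, Il7r -0.44 ± 0.24 and Il2ra -0.37 ± 0.27, none past the threshold. Of 13 double-positive markers 3 rose and 1 fell, with Ets2 at 1.61 ± 0.18 and Aqp11 at -1.26 ± 0.19 (3 and 3 over the list alone; 0.973). Of 15 mature T-cell markers 2 rose, also over the list alone, Ctla4 (2.68 ± 0.33) and Icos (2.39 ± 0.58; camera adjusted p = 0.348). Of 10 gamma-delta markers 2 rose, Id3 and 5830411N06Rik (at least 1.38-fold), and 3 fell, among them Cpa3 and Sox13 (-1.49 ± 0.20), with 5 and 3 over the list alone (0.814). For the gamma-delta list the median, and for the double-positive list the mean, was above 0 while camera's direction was down.

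Of 18 natural killer and innate lymphoid markers 10 rose and none fell, 15 adjusted over the list alone (camera adjusted p = 5.57e-09; adjusted p = 0.287 with an estimated correlation; fry 0.00439). They included Il18r1 (2.64 ± 0.37), Xcl1 (2.41 ± 0.42), Klre1 (2.11 ± 0.39) and Klrd1 (2.04 ± 0.28). Of 16 dendritic markers 1 rose, H2-DMa (1.95 ± 0.40), and 2 rose and 1 fell over the list alone (0.0502), and of 13 B-lineage markers 1 rose, Cd72 (2.22 ± 0.37), also over the list alone (0.488). Of 5 stromal markers 2 fell, over all genes and over the list alone, Pdgfrb (-2.43 ± 0.58) and Pecam1 (-1.12 ± 0.22; camera adjusted p = 0.0273; adjusted p = 0.287 with an estimated correlation; fry 0.00466). The 4 sex-linked genes gave no call.

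The 30 genes of S phase and mitosis passed camera as higher (adjusted p = 0.00571; adjusted p = 0.65 with an estimated correlation; fry 0.137), while no single member passed limma's test over all genes or over the list alone. The list's call ended without Lmo2 replicate 1 (0.169). Of 15 genes linked to quiescence 4 fell and 1 rose (6 and 3 over the list alone; 0.213): Cdkn2a was at least 2.12-fold lower, Foxo3 (-1.43 ± 0.20) and Trp53inp1 (-0.97 ± 0.18) fell, and Cdkn1a rose by 2.09 ± 0.35. In IL-7 and KIT signalling Stat5a fell by 1.81 ± 0.22 with Kit, and Cish, a target of STAT5, rose by 2.17 ± 0.33 (2 of 12 down and 1 up, 2 and 3 over the list alone; 0.756). In the BCL-2 family Bbc3 fell by 1.29 ± 0.23 and Bcl2a1b and Bcl2a1d rose by 1.94 ± 0.29 and 1.86 ± 0.35 (1 of 14 down and 2 up, 1 and 4 over the list alone; 0.0502). Bcl2 gave 0.59 ± 0.45 (-0.11 without Lmo2 replicate 2), Myc 0.11 ± 0.30 and Cdkn1b -0.27 ± 0.53 (0.31 without Lmo2 replicate 1). None of 23 interferon-stimulated genes passed over all genes or over the list alone (camera adjusted p = 0.814). Of 14 stress genes Egr2 rose by 1.87 ± 0.37 and Dnajb1 fell by 0.67 ± 0.16, the only 2 past the threshold over all genes, with 1 up and 1 down over the list alone too (0.348). The quiescence and BCL-2 family lists, which camera did not call, passed fry (adjusted p = 0.00439 and 0.0103).

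With only the 2 groups compared in the fit, 615 genes changed, and Bcl2a1d, Cd9, Id3, Klre1, Icos, Pdgfrb, Pecam1, Dnajb1 and 5830411N06Rik lost their call. With arrays scaled to a common median, 696 changed, and Cbfa2t3, Slc14a1, Trp53inp1, Pecam1 and Dnajb1 lost theirs, as did Bcl6 without Lmo2 replicate 1 or 3. Gata3 gained a call in 6 alternatives, and Bcl11a with arrays scaled to a common median and without Lmo2 replicate 1 (1.99; adjusted p = 0.0179). Without Lmo2 replicate 3 Il2ra gave -0.02, Il7r -0.19, Hes1 -0.35, Myc -0.23 and Dtx1 0.62, and Mef2c gave 0.71 without knockout replicate 2.

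The changes in the 2 comparisons above ran in opposite directions. Of the genes changed in both, 770 went opposite ways and 0 went the same way. Fewer went opposite ways under median scaling, with only the groups compared and with the replicate block, as given with the processing below. These 770 split into 435 that were up on Lmo2 arrays against wild-type and down without Lyl1, where independent lists would give 38.8, and 335 that were down and then up, where they would give 29.7. Across genes, which are not independent replicates, the log2 changes correlated at -0.801, against -0.579 for unchanged groups in 100 simulated draws. The covariance was -0.334 against a simulated -0.0423, a difference of -0.292. Both comparisons use the same 3 Lmo2 arrays, too few to split, so part of the excess may come from those shared arrays. Every simulated array had the same spread per gene. The Lmo2 arrays were more variable, correlating at 0.945 to 0.967 among themselves against 0.982 to 0.990 for knockout arrays. The simulated values may therefore understate chance here, and how much of the gap would remain was not tested.

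**Figure D2:**
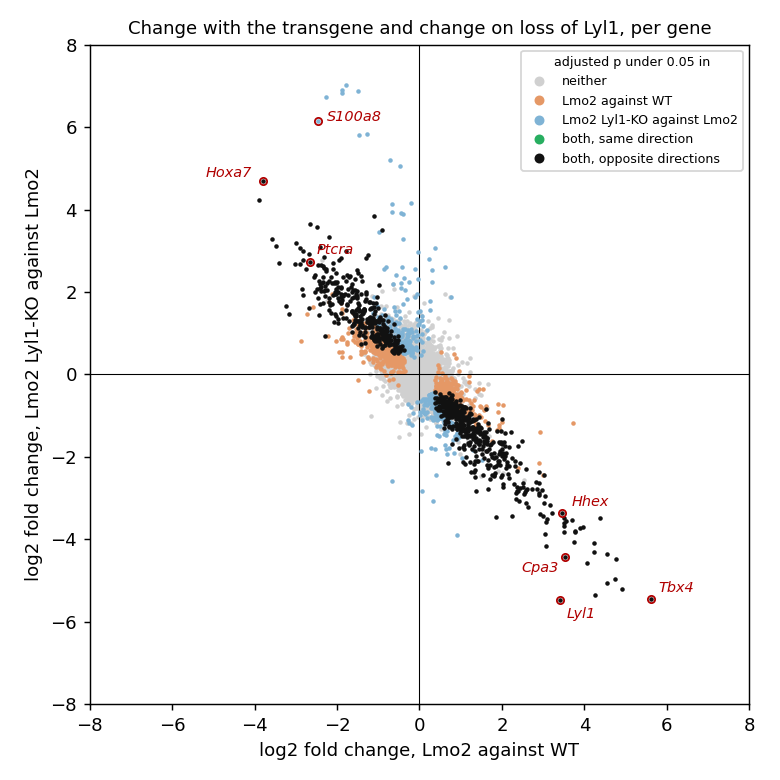
Log2 change of each gene for Lmo2 against wild-type arrays (x axis) and for Lmo2 Lyl1-knockout against Lmo2 arrays (y axis), with genes past the threshold in both and in opposite directions in black, in 1 comparison in orange or blue and in neither in grey. The 770 black genes lie on both sides of 0, with Hhex, Cpa3, Lyl1 and Tbx4 at the lower right and Hoxa7 and Ptcra at the upper left.

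Lmo2 Lyl1-knockout against wild-type arrays measured the transgene and the loss of Lyl1 together. No group lacked Lyl1 without the transgene. The comparison therefore cannot tell what remains of the transgene's effect from an effect of losing Lyl1 itself. Here 109 genes changed, 67 up and 42 down, with 55 and 31 of them at least 2-fold. Hhex gave 0.10 ± 0.22 on the log2 scale (SE; n = 3 against 6; adjusted p = 0.864), Nfe2 0.10 ± 0.27 (0.889), Ptcra 0.07 ± 0.34 (0.944) and Rag1 -0.22 ± 0.15 (0.559), so none of these 4 passed the threshold. Kit gave -1.12 ± 0.38 (0.255). Lyl1 was at least 3.5-fold lower (0.00351). With arrays scaled to a common median, 75.0% of changed genes were up, against 61.5% here.

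The 10 largest increases were Ngp (5.38 ± 0.77), Lcn2 (5.24 ± 0.87), Ltf (5.02 ± 0.81), Camp (4.94 ± 0.78), Retnlg (4.57 ± 0.94), Chil4 (4.57 ± 0.62), Fpr2 (4.48 ± 0.64), Chil3 (4.33 ± 0.61), Ifitm6, an interferon-induced membrane protein gene (3.97 ± 0.49), and Mmp9, a neutrophil gelatinase (3.49 ± 0.58). Their adjusted p-values ran from 0.00194 to 0.0382. Of the 6 wild-type arrays, 2 detected Fpr2, 3 Retnlg and Ifitm6, 4 Chil4 and Mmp9, and 5 Ngp, Lcn2, Camp and Chil3. Of 27 myeloid markers 6 rose and none fell, 16 adjusted over the list alone (camera adjusted p = 4.07e-18; adjusted p = 0.194 with an estimated correlation; fry 0.0186). The mean of this list relative to the wild-type mean was 1.01, 2.51 and 2.50 on the 3 knockout arrays, from -0.55 to 0.70 on wild-type arrays and from -0.63 to -0.45 on Lmo2 arrays. S100a8 read 7.78 to 9.94 on wild-type replicates 1 to 3 and 10.99 to 12.79 on the NHD13-named wild-type arrays. Neither S100a8 (3.67; adjusted p = 0.123) nor S100a9 (4.45; 0.071) was past the threshold, and both depended on the wild-type set, at 5.13 (0.033) and 6.10 (0.0123) against replicates 1 to 3 alone and 2.22 (0.0902) and 2.80 (0.0406) against the NHD13-named arrays alone.

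**Figure D3:**
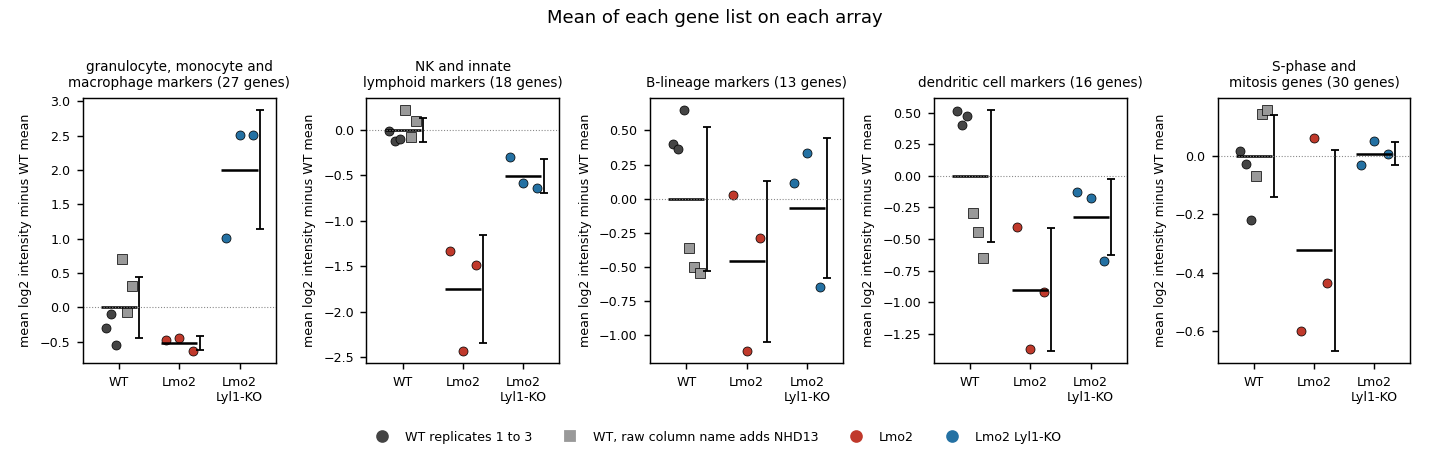
Mean log2 intensity of 5 gene lists on each of the 12 arrays, as the difference from the mean of the wild-type arrays. Myeloid markers were highest on the 3 Lmo2 Lyl1-knockout arrays, at 1.01 to 2.51, natural killer markers lowest on the 3 Lmo2 arrays, and B-lineage and dendritic markers separated the 2 sets of wild-type arrays.

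Of the 42 decreases, 31 were at least 2-fold. They included Fgf13 (-3.26 ± 0.51), Trim30a (-2.99 ± 0.56), Plekha7, a junction protein (-2.76 ± 0.47), Gprc5b (-2.05 ± 0.22) and Gpc1, a glypican (-2.03 ± 0.26). Trim30a and Plekha7 were detected on 1 knockout array. Pbx4, a homeobox gene, was at least 5.41-fold lower by its brightest probe (adjusted p = 2.01e-06), which was detected on no knockout array, with another of its probes detected on 1, and Zfp869, a zinc-finger gene, changed by -1.81 ± 0.14 (6.23e-05). Both lie on the chromosome that carries Lyl1. The 2 other probes of Pbx4 gave -0.91 and -0.74 and the 3 others of Zfp869 gave -0.51 to -0.18, none past the threshold, and neither were the other probes of Fgf13 (-1.81), Gprc5b (-0.61) and Aqp11 (-0.50). Dgkeos (-1.64 ± 0.13) and Klra10 (-1.70 ± 0.29) fell too. Of 18 natural killer and innate lymphoid markers 2 fell, Klra3 (-1.57 ± 0.30) and the transcription factor gene Tbx21 (-1.35 ± 0.21), and 9 adjusted over the list alone (camera adjusted p = 0.000176; adjusted p = 0.948 with an estimated correlation; fry 0.354), a call that ended against the NHD13-named arrays alone (0.0599).

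No other list passed camera, with adjusted p-values from 0.355 to 0.964. Their members past the threshold were few. Among 15 quiescence genes Btg1, an inhibitor of proliferation, rose by 1.34 ± 0.19. Hoxa5 rose by 1.10 ± 0.15 among 20 stem and progenitor genes, where Lyl1 fell (3 up and 2 down over the list alone). Of 12 Notch genes Hey1 rose (at least 1.4-fold), of 28 T-lineage genes Dntt, the terminal transferase, fell by 0.78 ± 0.14, and of 13 double-positive markers Aqp11 fell by 0.85 ± 0.17 with Dgkeos (1 up and 2 down over the list alone). Lyl1 was the only member past the threshold over all genes among the 12 LMO2 complex partners, the 14 early thymic progenitor genes and the 13 early T-cell precursor leukaemia genes (0 up and 1 down, 0 and 2, and 2 and 2 over the list alone). For Btg1, Hey1 and Dntt the counts over the list alone were the same. None passed among the 30 S-phase and mitosis, 14 BCL-2 family, 14 stress, 13 B-lineage, 15 mature T-cell and 4 sex-linked genes, over all genes or over the list alone. None passed over all genes among the 12 IL-7 and KIT, 23 interferon, 16 dendritic, 10 gamma-delta, 9 erythroid and 5 stromal genes, where the list alone gave 2 up and 2 down, 0 and 1, 0 and 1, 0 and 1, 1 and 0, and 0 and 1. Medians and camera's direction differed in sign for LMO2 partners, leukaemia genes, T-lineage, quiescence, S-phase and sex-linked genes, and the mean and camera's direction for stem and progenitor genes. The other key genes gave Mef2c -0.10 ± 0.51, Bcl11a -0.39 ± 0.43, Cbfa2t3 -0.32 ± 0.14, Gata3 -0.43 ± 0.21, Myc -0.64 ± 0.26, Bcl11b 0.00 ± 0.13, Notch1 0.02 ± 0.17 and Hes1 -0.26 ± 0.24, none past the threshold.

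Against replicates 1 to 3 alone 51 genes changed and against the NHD13-named arrays alone 1067, with 48 changed the same way against both (35 up, 13 down), 46 of them among the 109. Lyl1 (adjusted p = 0.0502), Klra10, Klra3, Tbx21, Fgf13, Trim30a, Plekha7, Hoxa5, Hey1, Dntt and Aqp11 lost their call against replicates 1 to 3 alone. Without knockout replicate 2 or 3 the count was 52 or 47, and Camp, Lcn2, Ltf, Mmp9, Retnlg, Fgf13, Trim30a, Klra10, Klra3, Tbx21, Dntt, Aqp11 and Hey1 lost their call without either. Kit gained a call with only the 2 groups compared and with array weights (adjusted p = 0.00656), and Cbfa2t3, Gata3 and Myc with array weights, while Mef2c gave 0.64 against the NHD13-named arrays alone (0.341). Without knockout replicate 2 Mef2c gave -0.48, Bcl11a -0.61 and Hhex -0.12, and Nfe2 gave 0.47 without replicate 1.

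Genes changed the same way in Lmo2 and in Lmo2 Lyl1-knockout arrays, each against wild-type, numbered 18. This count moved widely with the set of wild-type arrays, with array weights and without single knockout arrays, as given with the processing below. Of the 18 genes 7 were up, where independent lists would give 4.46, and 11 down, where they would give 2.49. Across genes the log2 changes correlated at 0.150, against 0.331 for unchanged groups sharing the wild-type arrays, and the covariance was 0.0379 against a simulated 0.0209. With the wild-type arrays divided into 2 sets of 3, so that no array was shared, the correlation over the 20 divisions ran from -0.1 to 0.125 with a median of 0.081, and from 3 to 72 genes were shared. Both the -0.1 and the 72 came from Lmo2 arrays set against replicates 1 to 3 and knockout arrays against the NHD13-named arrays. The reverse division gave -0.05 and 16 genes. Knockout arrays against Lmo2 and against wild-type arrays shared 82 genes changed the same way, 54 up and 28 down, where independent lists would give 3.19 and 2.33. The correlation was 0.473, against 0.577 simulated, and the covariance 0.134 against 0.0421. These 2 share the 3 knockout arrays, which are too few to split, so part of the excess may come from them. All simulated values in this paragraph also rest on an equal spread for every array, which the groups did not have, so they are not exact chance values.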

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

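Of the tests in this part, those of a lower thymocyte share, of normalization, of the neighbours of Lyl1 and of B and dendritic cells were chosen after the result was seen; those of further granulocyte genes, of sex and of other splits of the arrays were set before.

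The myeloid list of granulocyte, monocyte and macrophage markers was higher on Lmo2 Lyl1-knockout than on wild-type arrays by a mean of 2.01 ± 0.53 on the log2 scale, with 6 of 27 genes past the threshold (camera adjusted p = 4.07e-18, or 0.194 with an estimated correlation). A lower share of thymocytes that raised all other cell types alike is argued against as the whole cause. It would raise the B-lineage, dendritic and natural killer lists too, and the highest of these, the B-lineage list, changed by -0.067 (a gap of 2.07 ± 0.75). The test cannot speak on a share lowered by granulocytes alone, which would not raise those lists. Normalization is argued against too, since the lowest mean over 3 other normalizations was 1.385. Granulocytes among the sorted cells remain a candidate explanation. The mean over 18 measured genes of a further granulocyte list, from which 2 genes already named or on the myeloid list were left out, was higher by 1.54 ± 0.46. This mean was at 0.66, 2.01 and 1.94 on the 3 knockout arrays against -0.32 to 0.43 on wild-type and 0.09 to 0.18 on Lmo2 arrays. Of the 18 genes, 8 were past the threshold as higher than on wild-type arrays and 0 as lower. A sort for cells without CD4 and CD8 would not by itself remove granulocytes, and whether their number or the thymocytes' own expression differed, with the Lyl1 genotype as the biological explanation, stays open.

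Genes near Lyl1 were frequent among those changed the same way in Lmo2 Lyl1-knockout arrays against wild-type and against Lmo2 arrays, with 6 of the 200 nearest tested genes (3%) against 0.717% of the other genes (one-sided Fisher's exact test, p = 0.00411): Pgpep1, Smim7, Usp38, Inpp4b, Farsa and Wdr83os. An effect of the targeted allele on the closest genes alone is argued against as the cause of all 6, since 5 of the 190 genes beyond the nearest 10 changed (2.63%; one-sided Fisher's exact test, p = 0.0141), but such an effect stays open for the nearest 10, of which 4 changed for knockout against Lmo2 arrays (40% against 10.2%; same exact test, p = 0.014), where the 190 gave 10.5% (p = 0.485). Over the whole chromosome it was 15 of 548 genes, which include Pbx4 and Zfp869, whose values had been seen before the test was chosen, and Hp and Mcemp1 of the further granulocyte list, and without all genes named by the rule and all myeloid and granulocyte markers it was 11 of 541 (2.03% against 0.652% elsewhere with none left out there; one-sided Fisher's exact test, p = 0.00166). Within single comparisons, the share of the 200 nearest that changed was 3% against 0.979% for knockout against wild-type arrays (same exact test, p = 0.0162; whole chromosome without the same genes 2.22% against 0.913%, p = 0.00652), 12% against 10.2% for knockout against Lmo2 arrays (p = 0.24; whole chromosome 8.32% against 10.3%, p = 0.946), and 8% against 12.7% for Lmo2 against wild-type arrays (p = 0.985), where the Lyl1 allele does not differ by the labels. DNA of another mouse strain carried along with the targeted allele may account for some of these genes, by altered expression or, as the smaller changes of other Pbx4 and Zfp869 probes leave open, by altered probe binding, and an effect of Lyl1 on them stays open.

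The NHD13-named wild-type arrays differed from wild-type replicates 1 to 3 in 1609 genes, 857 higher and 752 lower, which are samples of 1 group by the labels. Xist, Eif2s3y and Kdm5d divided them as female and male mice, though Uty did not, but over 1553 differing autosomal genes the slope of the sex difference in the other 2 groups on this difference was 0.017 ± 0.18 (jackknife SE over 6 arrays), so sex alone is argued against as the whole cause. Fewer B-lineage and dendritic cells, whose markers were lower in 7 of 13 and 10 of 16 genes, are argued against as the whole cause by the 196 genes that were at least 2-fold higher. Of 27 myeloid markers 9 were higher and 1 lower, and of 14 stress genes 7 were higher and 2 lower, and neither was tested as a cause. A different colony or array batch could not be tested, and no biological explanation other than sex and fewer B-lineage and dendritic cells was tested.

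Other divisions of the arrays into groups of the same sizes were fitted. For Lmo2 against wild-type arrays, 1 of 84 splits, the real one, gave as many genes as 1324. The highest other gave 1238, with the NHD13-named arrays as the first group. The share of the real split is under 0.05. The wild-type arrays form 2 sets that differ, however, so the arrays are not interchangeable and this share cannot exclude chance. For Lmo2 Lyl1-knockout against wild-type arrays, 2 of 84 splits gave at least the real 109 genes. The other one was the split with the NHD13-named arrays as the first group, at 1698 genes, which points to a structure of the samples. This share is under 0.05 as well, but with such a structure it cannot exclude chance either. Within the sets of wild-type arrays the counts were 51 and 1067. For Lmo2 Lyl1-knockout against Lmo2 arrays the real split gave 1084 genes and the highest other 1; there are 10 splits, of which 1 was as large, too few for a share under 0.05.

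The Cbfa2t3 value of 1 NHD13-named array, 10.37, lay apart from the other wild-type arrays at 10.02 to 10.14. The mean of the quiescence list on wild-type replicate 2, 0.073, lay apart from the others at -0.037 to 0.002. These were 2 of 46 values tested for such gaps among the wild-type arrays, where chance gives about 1 in 20. Among the 3525 probes with no single gene name, which the report leaves out, 254 were past the threshold for Lmo2 against wild-type arrays (119 up, 135 down), 201 for Lmo2 Lyl1-knockout against Lmo2 arrays (110 up, 91 down) and 21 for Lmo2 Lyl1-knockout against wild-type arrays (7 up, 14 down).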

How the results depend on the processing

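The alternatives with 1 set of wild-type arrays and with sex as a term were chosen after seeing the data; all others were set before. The authors' value table gave 1319, 1090 and 110 changed genes for Lmo2 against wild-type, knockout against Lmo2 and knockout against wild-type arrays, of which 1309, 1082 and 109 were shared with the 1324, 1084 and 109 reported, and no named gene lost its call. Median scaling gave 775 and 696 in the first 2 comparisons, 496 of 770 reversed genes, 10 of 18 genes changed the same way, and 8 lists in place of 4 for knockout against Lmo2 arrays. With only the groups compared, 615 genes changed for knockout against Lmo2 and 186 for knockout against wild-type arrays, with 455 reversed and 30 changed the same way. This fit has fewer samples and its own estimate of the spread, and the cause of these moves, which went both ways, was not tested. Array weights gave 2392 genes for knockout against wild-type arrays, 322 changed the same way, and 2 lists for Lmo2 against wild-type arrays; they favour the NHD13-named arrays (1.85 to 2.12) over the other wild-type arrays (0.46 to 0.73). Lists called for Lmo2 against wild-type arrays numbered 8 at detection p under 0.01 and 9 with every probe on its own, and the latter gave 10 for knockout against Lmo2 arrays.

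With wild-type replicates 1 to 3 alone the counts were 750 and 51 against wild-type, 4 changed the same way and 8 lists called for knockout against wild-type arrays in place of 2. With the NHD13-named arrays alone they were 2429 and 1067, 641 changed the same way, and 2 and 1 lists called. With sex as a term, 28 genes changed the same way, and 1688 changed for Lmo2 against wild-type arrays. Sex was read from Xist, which divides the wild-type arrays just as the NHD13 name does. The sex term therefore also takes up the difference between the 2 wild-type sets. The cause of the differences under median scaling, the list settings and sex was not tested. Named genes lost their call in 35 cases with the replicate block, 28 with replicates 1 to 3 alone, 24 and 21 without knockout replicates 2 and 3, 21 under median scaling, 19 with only the groups compared, 7 with the NHD13-named arrays alone, 0 with sex as a term and at most 17 otherwise. No gene past the threshold changed direction; some below it did.

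The replicate block gave 605 and 33 genes against wild-type arrays, 463 reversed, 6 changed the same way and 7 lists called in each comparison with wild-type arrays. The NHD13-named arrays were given no number there and drop out of that fit. No pairing by number was seen. With each gene's group mean subtracted, the values of same-numbered arrays correlated at -0.306 to 0.17. Not every array correlated best with its own number. So few arrays cannot exclude a pairing. No slide block was run, as no slide is given in the sources used here.

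Leaving out each array in turn gave 1001 to 1361 and 749 to 1257 genes in the first 2 comparisons and 47 to 143 in the third, with 47 without knockout replicate 3 and 52 without replicate 2. Reversed genes ran from 583 to 879 and those changed the same way from 6 to 24, with 8 without knockout replicate 2 and 6 without replicate 3. Lists called ran from 2 to 6, 4 to 6 and 2 to 3, with 2 without Lmo2 replicate 1 or 3. The interferon list's mean for knockout against Lmo2 arrays ran from -0.203 to 0.386; without Lmo2 replicate 1 it was higher (adjusted p = 0.0467), which follows from that array's high value. Brightness over background and the number of arrays limit all of these.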

Other observations

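The genes in this part were chosen after their values were seen. The T-cell receptor beta segment Trbv13-1 read 7.65, 5.76 and 7.08 on the 3 Lmo2 arrays against 9.94 to 11.12 on wild-type arrays. The gamma segment Trgv5 read 12.73 on Lmo2 replicate 1 and 4.56 and 4.99 on the other Lmo2 arrays, against 7.02 to 7.81 on wild-type and 7.72 to 8.39 on Lmo2 Lyl1-knockout arrays. Trgv7 read 12, 5.00 and 4.89 on the same Lmo2 arrays, against 6.82 to 7.60 and 7.32 to 7.64. Trgv4 read 13.49, 11.75 and 13.98 on the Lmo2 arrays against 12.83 to 13.27 on wild-type arrays, and Trbv13-2 read 14.11 to 14.65 on all 12 arrays, near the top of the scale. Of these 5 only Trbv13-1 was past the threshold in any comparison (-3.90 ± 0.37 for Lmo2 against wild-type; limma adjusted p = 2.05e-05); Trgv4 gave 0.04 ± 0.36 (0.966) and Trbv13-2 -0.20 ± 0.12 (0.308).

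The C-type lectin genes Clec4d and Clec4e, which macrophages and neutrophils are known to express and which the further granulocyte list holds, were higher on Lmo2 than on wild-type arrays. Clec4d rose by 2.92 ± 0.36 against wild-type arrays (limma adjusted p = 0.000186) and Clec4e by 3.54 ± 0.43 (0.000162). For Lmo2 Lyl1-knockout against Lmo2 arrays Clec4e changed by -3.55 ± 0.50 (0.000565) and Clec4d by -1.40 ± 0.42 (0.054).

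Within the Hoxa genes, Hoxa5 was not detected on any Lmo2 array and was past the threshold as lower than on wild-type arrays (adjusted p = 6.35e-07), like Hoxa7. Hoxa4 gave -0.48 ± 0.30 (0.339) and Hoxa13 -0.08 ± 0.20 (0.835). On wild-type arrays Hoxa4 read 4.84 to 6.26 and Hoxa13 5.76 to 6.38, where the lowest detected probes read 5.10 to 5.37. So near background, neither could show a fall as large as that of Hoxa7. The mean of the interferon list, relative to wild-type arrays, was 0.97 on Lmo2 replicate 1 and -0.21 and -0.20 on the other Lmo2 arrays. Xist read 4.45 to 4.55 on wild-type replicates 1 to 3 and 11.34 to 11.89 on the NHD13-named wild-type arrays, and by Xist, Eif2s3y and Kdm5d the other 2 groups held mice of both sexes.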
